A study of Equus caballus with 8 samples.

How the data were processed

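Small RNA sequencing was carried out on exosomes precipitated from the seminal plasma of stallions. The 8 libraries fall into 3 groups by the submitters' labels: before challenge (n = 3), 86 days after experimental infection with equine arteritis virus (n = 3) and 726 days after it, labelled as long-term persistent infection (n = 2). Exosomes were isolated with a precipitation reagent, RNA was extracted with an exosome RNA kit, and size-selected libraries were sequenced as single reads, per the labels' protocols. The submitters' processing notes name bcl2fastq and Trim Galore, without versions.

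The deposited tables, one per library, hold whole-number read counts that the authors obtained with miRDeep2 for the mature, loop and star parts of each precursor and for the precursor as a whole, without normalization, per the file headers. Consensus sequences and coordinates are given beside them. Each table has a section of annotated equine miRNAs with a call, a section of annotated precursors without a call, and a section of candidate loci outside the annotation. The tables state that 690 equine mature miRNAs were searched. The genome build, the miRNA annotation release and the version of the caller are not given in the sources used here, so coordinates are printed as the files give them, counted from 1.

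Because a hairpin can be listed with either arm as its mature sequence, the same molecule was followed in every library by its sequence. Sequences were joined where they matched without a mismatch over at least 16 bases with starts at most 3 bases apart, and the more abundant arm was kept. This definition was set after the files were seen and before any test. A label ending in 3p or 5p gives the arm counted where the listed names carry an arm; eca-miR-34b-3p, for example, is listed under the name eca-miR-34b-5p. A miRNA listed at several precursor loci took the largest count. This gave 370 molecules, of which 311 had a listed name and 59 did not; the latter are printed by sequence. Of the 245 listings without a call, 186 could be joined to a named molecule. A molecule that a table does not list was counted as 0 there. Loci of one miRNA, and near-identical family members such as those of let-7, can share reads, so their separate values are uncertain.

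Depth ranged from 594015 to 3356469 mature miRNA reads per library. A count of 0 allows up to 3 reads per library, or 0.894 to 5.05 CPM (reads scaled to the total of the library) before TMM scaling. Such floors cover counting error only, since the reads carry no molecular identifiers.

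Groups were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10). All 8 libraries shared one fit with group as its only term, and p-values were adjusted by Benjamini and Hochberg at 0.05; 229 molecules were tested. Levels are TMM-scaled CPM, mean ± SD. Differences within a stallion are on the log2 scale with 0.5 CPM added. For eca-miR-128, named in the series title, an exact two-sided permutation test compared log2 CPM (prior count 1) in the 2 libraries of day 726 with the other 6, over 28 splits. From 14 miRNA lists, 13 had at least 3 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives. The red blood cell list had 2 tested members and was not tested. It also names miR-451, miR-451a and miR-144, and no molecule with reads carried these names. List members were matched by listed name, so molecules without a name and candidate loci outside the annotation are in no list. A list can therefore lack members that were left unnamed. Names also had to match exactly apart from the arm. The testis and sperm list, which names miR-506 and miR-514, therefore leaves out the tested eca-miR-506a and eca-miR-514a. Lists and tests were fixed before the data were examined, but the count was not. The planned count was the mature read count as deposited, largest over loci, and following molecules by sequence departs from it. The alternative nearest to the plan is the mature column as listed. Lists share members: the leukocyte and inflammation lists share eca-miR-146a, eca-miR-146b-5p, eca-miR-155 and eca-miR-223, eca-miR-92a is in the endothelial and miR-17-92 lists, and eca-miR-363 is in the red blood cell and miR-17-92 lists.

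The miRNAs named in a comparison are eca-miR-128, up to 10 past the threshold in each direction by fold change, and, where fewer than 10 passed, those of smallest unadjusted p until 10 were named. List members named are up to 3 per list with the highest mean CPM, and the data description names the 10 most abundant miRNAs.

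Stallion codes in the sample titles (L136, L139, L140) recur across groups and were read as the same animals, so the codes pair the libraries; L139 has no library at day 726 among those analysed. The labels do not say more about the animals. Deviations from the group means correlated between libraries of the same stallion at -0.24 to 0.16 (mean -0.0031, 7 pairs) and between different stallions at -0.23 to 0.24. With 2 libraries at day 726 the deviations there mirror each other, so these values cannot show the absence of a stallion effect. Between pre-challenge and day 86 the same stallion gave 0.15 (L136), 0.14 (L139) and -0.01 (L140). No pair of libraries within a group differed by less than sampling noise (chi-square per degree of freedom at least 601.3).

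Alternatives covered scaling (RLE, library totals only, upper quartile), filters (none, mean count of at least 10), DESeq2 1.42.0, limma voom, a replicate block for stallion, fits of only the groups compared, sums and means over loci, total precursor reads and leaving out each library. Added after seeing the data were the mature column as listed, called listings only, both L139 libraries left out, the DLK1-DIO3 list without eca-miR-545 (with and without the replicate block), and a permutation of eca-miR-128 within stallions.

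The tests were also run on simulated data. In 20 simulated sets of 229 miRNAs with 40 changed at day 726, the comparison of day 726 with day 86 recovered 17.1% of 4-fold and 66.8% of 16-fold changes, with 5.20% false calls. The comparison of day 726 with pre-challenge recovered 15.7% and 66.0%, with 4.13% false calls. For day 86 against pre-challenge, with no change simulated, 0.05 calls were made per set. A list of 5 members shifted 4-fold was called by camera in 20 of 20 sets, and in 19 with an estimated correlation. Simulated members varied independently, so this does not cover lists whose members vary together.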

Results

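Exosomal small RNA was profiled in semen of stallions before and after experimental infection with equine arteritis virus, a virus that can persist in the male reproductive tract. The libraries before challenge held 2717856 (L136), 1132897 (L139) and 3356469 (L140) mature miRNA reads. Those at day 86 held 2422688 (L136), 594015 (L139) and 2399535 (L140), and those at day 726 held 2431860 (L136) and 1305323 (L140). Between 199 and 276 miRNAs had reads in a library.

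The most abundant miRNA was eca-let-7a, with a mean of 272649 ± 134600 CPM (SD, n = 8), followed by eca-miR-21 at 172350 ± 63160 and eca-miR-10b at 103213 ± 50578 CPM. Next came eca-let-7f, eca-miR-221, eca-miR-200c, eca-miR-26a, eca-miR-10a, eca-let-7g and eca-let-7c, from 53576 CPM down to 20561 CPM. The 10 most abundant molecules of each library took 72.2% to 85.4% of its reads. Epithelial miRNAs of the miR-200 and miR-205 group, which included eca-miR-200c, eca-miR-200a and eca-miR-205, held 7.75% ± 0.807 of reads before challenge (n = 3), 7.39% ± 2.57 at day 86 (n = 3) and 7.98% ± 0.559 at day 726 (n = 2). The red blood cell miRNA eca-miR-486-5p stood at 397.4 ± 256.4, 211.2 ± 97.9 and 1107 ± 1480 CPM in the same order. Its day 726 libraries were the lowest (L136, 60.9 CPM) and the highest (L140, 2153 CPM) of all 8. The other named member of that list with reads, eca-miR-363, was at 1.32 ± 2.28, 2.82 ± 4.88 and 5.76 ± 2.83 CPM.

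The series title ties eca-miR-128 to long-term persistent infection. This miRNA, with the sequence ucacagugaaccggucucuuu, is listed at 2 loci, the one with most reads on chromosome 18 from 19492358 to 19492413 on the plus strand; the genome build is not given in the sources used here and the files name no host gene. It was measured at 3128 ± 1177 CPM before challenge (n = 3), 4748 ± 1970 CPM at day 86 (n = 3) and 781 ± 204 CPM at day 726 (n = 2). Both day 726 libraries, at 925.2 and 636.7 CPM, lay below the 6 earlier ones, which ranged from 2328 to 6749 CPM. The difference between day 726 and the earlier libraries was -2.23 on the log2 scale, 4.68-fold lower (exact two-sided permutation test, p = 0.0357, the smallest that 28 splits allow). These splits exchange libraries freely between stallions. With exchange only among the libraries of a stallion, 9 arrangements remain, the exact p is 0.111, the smallest they allow, and the test cannot reach 0.05. How the study chose this miRNA is not given in the sources used here. Since it may have been chosen on these samples, neither test counts as independent evidence.

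**Figure D1:**
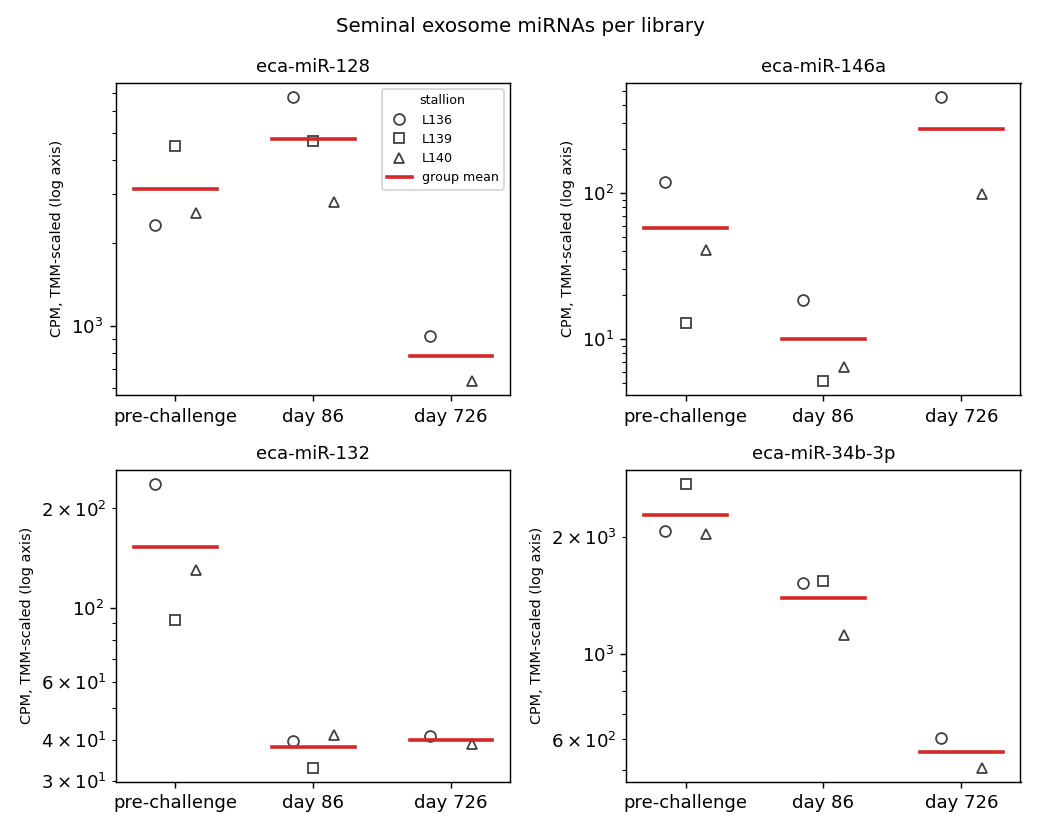
TMM-scaled CPM on a log axis for eca-miR-128, eca-miR-146a, eca-miR-132 and eca-miR-34b-3p in each library before challenge (n = 3), at day 86 (n = 3) and at day 726 (n = 2), with a symbol for each stallion and a red line for the group mean. The 2 libraries at day 726 sit at 925.2 and 636.7 CPM for eca-miR-128, below the 6 others.

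The comparison of day 86 with pre-challenge asks how exosomal miRNAs stand in infected stallions against their level before infection. No miRNA passed the threshold: 0 of 229 by edgeR's quasi-likelihood test, 0 by DESeq2 and 0 by limma voom, with 8 at an unadjusted p under 0.05 where chance would give about 11.5. All 8 had lower levels at day 86. eca-miR-132, a miRNA induced in inflammatory signalling, stood at 153.2 ± 75.2 CPM before challenge and 37.9 ± 4.40 CPM at day 86 (log2 fold change -2.01, SE 0.64, edgeR adjusted p = 0.501), and was lower in 3 of 3 stallions. eca-miR-139-5p was at 15.5 ± 7.29 CPM before challenge and was listed in no day 86 library, which makes it at least 5.69-fold lower against a floor of 3 reads per library (adjusted p = 0.501). eca-miR-1249, at 7.01 ± 6.50 CPM before challenge, was also at 0, at least 2.57-fold lower in the means (adjusted p = 0.836). Its pre-challenge level came from L136 (8.18 CPM) and L139 (12.8 CPM), and L140 had 0 reads at either time. eca-miR-146a, a feedback regulator of innate immune signalling, was at 57.3 ± 54.7 and 10.04 ± 7.34 CPM, and its relative eca-miR-146b-5p at 549 ± 608.1 and 171.5 ± 133.5 CPM. eca-miR-340-5p was at 900.9 ± 472.4 and 364.2 ± 210.9 CPM, and the unnamed molecule aaaccguuaccauuacuguguu at 11.2 ± 19.5 and 0.176 ± 0.305 CPM, with all 128 of its pre-challenge reads in L136. eca-miR-98 of the let-7 family was at 6363 ± 4430 before challenge and 15450 ± 13453 CPM at day 86. Without the pre-challenge library of L136 the log2 fold change of eca-miR-146b-5p went from -1.67 to -0.07 and that of eca-miR-146a from -2.48 to -1.25. Without the day 86 library of L136 that of eca-miR-98 went from 1.28 to 0.30. Adjusted p-values of the miRNAs named here ran from 0.501 to 0.923, the last for eca-miR-128 (log2 fold change 0.60, SE 0.48). Without the pre-challenge library of L139, 1 miRNA passed, eca-miR-143 of the muscle and stroma list, with a log2 fold change of 7.85. The pre-challenge libraries then left held 5 (L136) and 0 (L140) reads of it. With the L139 library the value was 1.44 (SE 1.35, edgeR adjusted p = 0.951).

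Among the lists, that of the let-7 family and miR-98 was higher at day 86 (7 of 7 members with a positive log2 fold change, median 0.73, camera adjusted p = 0.00465), with adjusted p = 0.403 with an estimated correlation. Of its 7 members, 0 passed over all miRNAs and 0 adjusted over the list alone. eca-let-7a was at 265004 ± 191168 and 356450 ± 55240 CPM, eca-let-7f at 44977 ± 27467 and 77219 ± 30389 CPM, and eca-let-7g at 19138 ± 10629 and 32544 ± 13442 CPM. The let-7 share of reads was 54.8% in the pre-challenge library of L139, above all 3 day 86 libraries, and without the pre-challenge library of L136, at 22.1%, the list's adjusted p was 0.305 (3.60e-05 to 0.484 over all alternatives). With that library left out 0 lists passed, without the day 86 library of L136 4 passed, and 2 passed without the pre-challenge library of L140, the day 86 library of L140 or either day 726 library. With stallion as a replicate block 2 lists passed, the muscle and stroma list being the other (adjusted p = 0.0169; 0.383 with an estimated correlation).

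**Figure D2:**
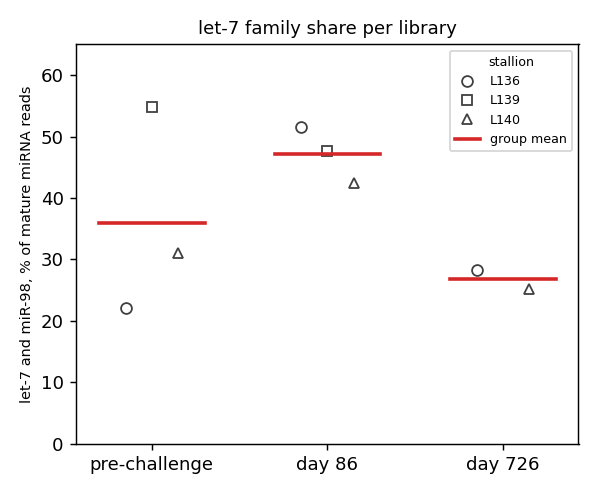
Share of mature miRNA reads, in percent on a linear axis, held by the let-7 family and miR-98 in each library, with a symbol for each stallion and a red line for the group mean. Shares were 42.5% to 51.5% at day 86, 25.2% and 28.3% at day 726, and 22.1% to 54.8% before challenge.

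No other list passed. The testis and sperm list had 4 of 5 members with lower values at day 86 (camera adjusted p = 0.103), and 1 passed adjusted over the list alone; eca-miR-449a, of the miR-34 and miR-449 family of ciliated and germ cells, was at 13279 ± 9782 and 3619 ± 2162 CPM, eca-miR-34b-3p at 2282 ± 398.4 and 1392 ± 241.2 CPM, and eca-miR-34c at 2301 ± 1991 and 887.3 ± 487.7 CPM. Without the pre-challenge library of L136 the log2 fold change of eca-miR-449a went from -1.88 to -1.06 and that of eca-miR-34c from -1.38 to -0.32. Left out of this list by exact name matching, eca-miR-506a was at 92.2 ± 13.7 before challenge and 109.4 ± 40.8 CPM at day 86. eca-miR-514a, also left out, was at 4.5 ± 1.6 and 1.76 ± 3.05 CPM. In the leukocyte list 6 of 8 members had lower values (adjusted p = 0.161), with eca-miR-181a at 5696 ± 2541 and 3744 ± 2817 CPM. The list of miR-17-92 clusters had 11 of 12 lower (adjusted p = 0.103), the inflammation list 10 of 14 lower (0.221), and the muscle and stroma list 4 of 6 higher (0.103). For the epithelial list 7 of 9 members were higher (adjusted p = 0.161), for the miR-10, miR-100 and miR-125 list 6 of 9 (0.166), and for the DLK1-DIO3 list 9 of 20 (0.460). This list as fixed holds eca-miR-545, which the files place on chromosome X and the other 19 on chromosome 24. Without it 9 of 19 were higher (adjusted p = 0.415). Higher values were found for 2 of 3 named members of the miR-30 family (camera adjusted p = 0.771). The miR-30 list leaves out the unnamed molecule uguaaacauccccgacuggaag. That molecule starts with the same bases as the 3 named members, uguaaacaucc, and had 279201 reads over all libraries, more than any of them. Of the endothelial list 2 of 5 were higher, of the neuroendocrine 1 of 6 and of the liver list 2 of 4 (0.848 each). The test pointed up where the median log2 fold change was negative for the DLK1-DIO3 (-0.13), endothelial (-0.27) and neuroendocrine (-0.28) lists; the mean was 0.59 for the endothelial list and also negative for the others. In all lists but that of testis and sperm, 0 members passed adjusted over the list alone.

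The comparison of day 726 with pre-challenge addresses long-term persistence. Again 0 of 229 miRNAs passed by edgeR, with 12 at an unadjusted p under 0.05; limma voom called 0, and DESeq2 called 1, eca-miR-34b-3p. That miRNA was at 2282 ± 398.4 CPM before challenge and 555.7 ± 68.5 CPM at day 726 (log2 fold change -2.04, SE 0.54, edgeR adjusted p = 0.345), lower in 2 of 2 stallions; its adjusted p was 0.00496 by DESeq2, in a range up to 1 over all alternatives. eca-miR-128 had a similar difference (log2 fold change -2.00, SE 0.58, adjusted p = 0.358), also lower in 2 of 2 stallions. eca-miR-132 was at 39.9 ± 1.53 CPM at day 726, eca-miR-34c at 657.5 ± 186.8 CPM and eca-miR-382, of the imprinted DLK1-DIO3 cluster, at 26.5 ± 0.840 against 97.0 ± 31.7 CPM. The 3' arm shared by eca-miR-199a and eca-miR-199b was at 80.3 ± 89.1 and 14.1 ± 9.86 CPM. Higher mean values at day 726 were found for eca-miR-146a (276.4 ± 251.9 CPM), eca-miR-23a (314.2 ± 273.1 against 81.8 ± 16.8 CPM) and eca-miR-23b (4773 ± 4972 against 1486 ± 512.7 CPM), and none of these 3 passed (each adjusted p = 0.637). Without the day 726 library of L140 the log2 fold change of eca-miR-23b went from 1.68 to -0.27 and that of eca-miR-23a from 1.94 to 0.55, and without that of L136 eca-miR-146a went from 2.26 to 0.88. For eca-miR-34c it went from -1.81 to -0.82 without the pre-challenge library of L136, and for the 3' arm of eca-miR-199a and eca-miR-199b from -2.48 to -1.04 without that of L139. eca-miR-143 had a log2 fold change of -4.17 (SE 1.84, adjusted p = 0.787), but its CPM was higher at day 726 in 2 of 2 stallions. That rested on few reads, 5 before challenge and 5 at day 726 in L136, and 0 and 7 in L140. The log2 fold change was 2.13 without the pre-challenge library of L139, which held 162 of its 167 reads in that group. With no filter eca-miR-143 passed (edgeR adjusted p = 0.0114).

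None of the 13 lists passed in this comparison by camera, with the estimated correlation or by fry. The testis and sperm list had 4 of 5 members lower (camera adjusted p = 0.218), and 1 passed adjusted over the list alone; in the other lists 0 did. All 7 let-7 members had lower values in the fit (camera adjusted p = 0.285), but the stallions differed. The list's share of reads rose in L136, from 22.1% before challenge to 28.3% at day 726, and fell in L140, from 31.0% to 25.2%. The pre-challenge library of L139, at 54.8%, has no day 726 partner. The leukocyte list had 5 of 8 members higher (camera adjusted p = 0.342) and the inflammation list 7 of 14 (0.372). The endothelial list had 4 of 5 higher (0.285) and the miR-30 family 3 of 3 named members (0.342). The muscle and stroma list had 4 of 6 lower and the DLK1-DIO3 list 14 of 20 lower (adjusted p = 0.285 for both). Without eca-miR-545 the latter had 14 of 19 lower (0.284). The miR-10, miR-100 and miR-125 list had 6 of 9 higher (adjusted p = 0.296), the epithelial list 6 of 9 higher (0.486), and the liver (2 of 4 higher), neuroendocrine (4 of 6) and miR-17-92 (4 of 12) lists had an adjusted p of 0.688. For the miR-17-92 list the test and the mean (0.079) were positive and the median negative (-0.14), and for the neuroendocrine list the mean alone was negative (-0.97). Without the pre-challenge library of L136 the let-7 list passed, and without that of L139 the testis and sperm list, 1 list in each case (adjusted p = 0.769 and 0.753 with an estimated correlation). eca-miR-192 of the liver list was at 100.6 ± 73.4 and 68.6 ± 5.52 CPM, and eca-miR-9a of the neuroendocrine list at 328.1 ± 416.9 and 448.6 ± 499.4 CPM, though lower at day 726 in 2 of 2 stallions.

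The comparison of day 726 with day 86 sets later against earlier infection. eca-miR-146a was the single miRNA that passed, at 10.04 ± 7.34 CPM at day 86 (n = 3) and 276.4 ± 251.9 CPM at day 726 (n = 2), 26.6-fold higher (log2 fold change 4.73, SE 0.98, edgeR adjusted p = 0.0338; 3.20 to 5.46 over all single libraries left out) and higher in 2 of 2 stallions. It lies on chromosome 14 from 19243273 to 19243330 on the minus strand, as the files give it. The day 86 libraries held 35 (L136), 3 (L139) and 14 (L140) reads of eca-miR-146a, where 3 is the floor per library. At day 726 it was at 454.5 CPM in L136 and 98.35 CPM in L140, the latter below the pre-challenge library of L136 (118.4 CPM). eca-miR-128 was 6.08-fold lower at day 726 (log2 fold change -2.60, SE 0.60), lower in 2 of 2 stallions, and its adjusted p of 0.0506 did not pass. It passed in 6 of 23 alternatives, among them those without the pre-challenge library of L136 (adjusted p = 0.0402) or of L139 (0.0297) and without the day 86 library of L140 (0.0114). The other miRNAs named did not pass either, with adjusted p from 0.167 to 0.277. Each passed in some alternatives, eca-miR-143 in 6, the 3' arm of eca-miR-199a and eca-miR-199b in 4, eca-miR-193b, eca-miR-98 and the unnamed molecule in 2, and eca-miR-101, eca-miR-191a and eca-miR-197 in 1. eca-miR-193b was at 7.22 ± 4.62 and 80.2 ± 44.9 CPM, eca-miR-197 at 39.8 ± 35.4 and 186.1 ± 38.8 CPM, and eca-miR-101 at 589.6 ± 277.1 and 2096 ± 1560 CPM. Without the day 726 library of L140 the log2 fold change of eca-miR-101 went from 1.83 to 0.65, and without the day 86 library of L136 that of eca-miR-98 from -2.49 to -1.56. Over all single libraries left out it spanned 2.59 to 4.04 for eca-miR-193b (3.41 with all), 1.87 to 3.27 for eca-miR-197 (2.21), -4.46 to -3.05 for the 3' arm of eca-miR-199a and eca-miR-199b (-3.44) and -6.49 to -5.10 for eca-miR-143 (-5.61). eca-miR-98 was at 15450 ± 13453 and 2757 ± 868.8 CPM, eca-miR-191a at 4197 ± 941.7 and 1136 ± 133 CPM, eca-miR-143 at 155.7 ± 95.6 and 3.21 ± 1.87 CPM, and the 3' arm of eca-miR-199a and eca-miR-199b at 155 ± 88.7 and 14.1 ± 9.86 CPM. The unnamed molecule aaaccguuaccauuacuguguu had 1 read at day 86, in L136, and 123 at day 726, in L140. Whether it is a listed miRNA left without a name, such as miR-451 of the red blood cell list, was not tested. The red blood cell miRNA eca-miR-486-5p was also highest in that L140 library, at 2153 CPM, against 60.9 CPM in L136 at day 726. Before challenge eca-miR-486-5p was likewise highest in L136 (691.4 CPM), the library that held the molecule's reads then. In all, 23 miRNAs had an unadjusted p under 0.05. DESeq2 called 4 miRNAs, eca-miR-146a, eca-miR-128, eca-miR-193b and the 3' arm of eca-miR-199a and eca-miR-199b, and limma voom called 0. The adjusted p of eca-miR-128 ranged from 0.00144 to 0.389 over all alternatives, and that of eca-miR-146a from 1.40e-05 to 0.350; the latter lost its call in 9 of 23. Single libraries whose absence ended it were the pre-challenge library of L140 (0.0852), the day 86 library of L139 (0.350) and the day 726 library of L136 (0.0863). The count of 1 miRNA became 0 without the pre-challenge library of L140 or the day 86 library of L139, 2 without the pre-challenge library of L136 or the day 726 library of L140, 4 without the pre-challenge library of L139, 6 without the day 726 library of L136, and 13 without the day 86 library of L140.

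By camera 2 lists were lower at day 726 than at day 86. All 7 let-7 members had negative values (median log2 fold change -1.32, adjusted p = 0.000922), and the adjusted p was 0.301 with an estimated correlation; 0 members passed over all miRNAs and 1 passed adjusted over the list alone. eca-let-7a was at 158416 ± 16894, eca-let-7f at 31009 ± 6802 and eca-let-7g at 12534 ± 2773 CPM at day 726. The muscle and stroma list had 4 of 6 members lower (adjusted p = 0.0256; 0.301 with an estimated correlation), and 2 passed adjusted over the list alone. Its median log2 fold change was -2.63, or -1.20 with the member at 0 in a group set to its bound, and eca-miR-1, a muscle miRNA, was at 57.4 ± 13.8 and 59.1 ± 3.32 CPM. By fry the muscle list and the miR-17-92 list passed (adjusted p = 0.0392 each). By camera with an estimated correlation both had an adjusted p of 0.301. The muscle call by camera was lost without the day 86 library of L139, leaving 1 list, and 4 lists passed without the day 726 library of L140. With stallion as a replicate block 5 lists passed: these 2 (adjusted p = 0.00779 each), the leukocyte and inflammation lists, higher at day 726, and the DLK1-DIO3 list, lower (adjusted p = 0.0437 each; 0.0390 for the latter without eca-miR-545). With an estimated correlation these 5 had an adjusted p of 0.352 to 0.515.

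Without the block, 7 of 8 leukocyte miRNAs had higher values (adjusted p = 0.118), with eca-miR-181a at 3744 ± 2817 and 8766 ± 710.6 CPM and eca-miR-155 at 3391 ± 761.7 and 6628 ± 5979 CPM. The higher mean of eca-miR-155 came from L136 alone, at 10856 CPM; L140, at 2400 CPM, lay below every day 86 library. The inflammation list had 11 of 14 higher (adjusted p = 0.145). In each of these lists 1 member, eca-miR-146a, passed both over all miRNAs and adjusted over the list alone. The miR-17-92 clusters had 12 of 12 higher (camera adjusted p = 0.144). Among them eca-miR-92a was at 1088 ± 1223 and 4070 ± 3925 CPM (1295 in L136 and 6846 in L140 at day 726). That L140 library was also the highest of all in the red blood cell miRNA eca-miR-486-5p. With no filter eca-miR-486-5p passed (log2 fold change 2.49, edgeR adjusted p = 0.00673), and with the filter and all libraries it did not. The stallions differed: from day 86 to day 726 it fell in L136, from 196.4 to 60.9 CPM, and rose in L140, from 121.5 to 2153 CPM. Without the day 726 library of L136 its log2 fold change was 3.34 with the filter. The DLK1-DIO3 list had 13 of 20 lower (camera adjusted p = 0.144), or 13 of 19 without eca-miR-545 (0.0985). Higher values were found for 3 of 5 endothelial members (camera adjusted p = 0.565) and 4 of 9 epithelial members (0.796). Of the named miR-30 members 3 of 3 were higher (0.796), of the testis list 2 of 5 and of the liver list 2 of 4 (0.808 each). The neuroendocrine list had 5 of 6 higher (0.865), and the miR-10, miR-100 and miR-125 list 5 of 9 (0.959). In the last of these the test pointed down while the median (0.25) and mean (0.072) were positive, and in the neuroendocrine list the mean (-0.52) was negative while the test and median were positive. In these lists 0 members passed adjusted over the list alone.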

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

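The tests of explanations given here were chosen after the results were seen. Of the 21 miRNAs named by p-value or by the series title, 4 had values on opposite sides of the pre-challenge level at days 86 and 726 in every stallion sampled then; others did so in their group means only and are not listed here. None of the 4 passed against pre-challenge at either time, and for eca-miR-128 the day 86 differences in L139 and L140 were only 0.06 and 0.12. For eca-miR-146a the difference between both effects was tested by the comparison of day 726 with day 86, and passed (log2 difference 4.73, edgeR adjusted p = 0.0338). For eca-miR-128 (-2.60), the 3' arm of eca-miR-199a/miR-199b-3p (-3.44) and eca-miR-193b (3.41) the test of the difference did not pass (adjusted p = 0.0506, 0.193 and 0.167).

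The lower level of eca-miR-128 at day 726 was set against a pair of technical explanations. The absence of an L139 library at day 726 is argued against by the values within L136 and L140, where the difference closest to 0 was -1.33. Scaling between libraries is argued against as the whole cause, since the difference closest to 0 under the 3 other scalings was -2.00. What stays open is anything shared by the day 726 samples, such as collection, storage or library handling, which the labels do not separate from infection time. Persistent infection remains an untested biological explanation.

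The higher level of eca-miR-146a at day 726 than at day 86 was compared with the other leukocyte miRNAs, 7 in number. Their median log2 fold change was 0.75 (SD 1.15 over members), below 4.73 by more than that spread, which argues against a general rise in leukocyte RNA as the whole cause. A rise stays open, since 6 of the 7 were higher and the list held 1.56% and 2.32% of reads at day 726 against 0.467% to 1.02% at day 86. The remaining member, eca-miR-142-5p, was lower (-2.15). Of these 7, the inflammation list also holds 3, and some, such as eca-miR-181a, are also made by other cells. Without each library in turn, the lowest fold change was 3.20 on the log2 scale, without the day 726 library of L136, so no single library made the whole difference, but the adjusted p was then 0.0863. A change within cells already present, or in handling of the day 726 samples, stays open.

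The higher let-7 list at day 86 than before challenge depended on how the members vary together, with an adjusted p of 0.403 with an estimated correlation, and on a single library, with an adjusted p of 0.305 without the pre-challenge library of L136. Both may account for the call, and an effect of infection remains untested. The 6 libraries make 10 splits, the real one included, too few for a share under 0.05. For the count of lists the real value was 1 and the highest of the other splits 3, and 5 of the 10, the real one among them, gave at least 1. For the count of miRNAs the real value was 0, which every split reaches, so the splits say nothing about it.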

How the results depend on the processing

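Alternatives added after seeing the data were the listed mature column, called listings only, both L139 libraries left out, the DLK1-DIO3 list without eca-miR-545 and a permutation within stallions. The cause of the changes below was not tested, except where fewer libraries limit the test. For day 86 against pre-challenge the count of miRNAs was 0 to 1 when leaving out each library and 0 under the other settings. For day 726 against pre-challenge it was 1 with no filter and with DESeq2. For day 726 against day 86 the count of 1 became 7 with no filter, 4 with DESeq2, 2 with means over loci and with only the groups compared, and 0 with the mean count filter, limma voom, sums over loci, the listed column, called listings and both L139 libraries left out; it was 0 to 13 when leaving out each library. eca-miR-146a kept its direction in all 23 alternatives and its call in 14, with adjusted p from 1.40e-05 to 0.350. With the listed mature column, the count nearest to the plan, its edgeR adjusted p was 0.220.

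eca-miR-128 was lower at day 726 than at day 86 in all 23 alternatives and passed in 6: log2 fold change -2.54 with no filter, -2.59 with DESeq2, -2.62 with means over loci and 3 of those leaving out a library, which spanned -2.94 to -2.33 (adjusted p over alternatives 0.00144 to 0.389). Its permutation difference was -2.45 to -2.00 when leaving out each library and -2.10 with both L139 libraries left out. With exchange within stallions, as a replicate block, it stayed at -2.23. With 1 library at day 726, 6 libraries in all, or exchange within stallions, the smallest possible p is 0.143, 0.0667 or 0.111, so these cannot pass; in the model fits a lone library was assumed to vary like the other groups.

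With the estimated correlation the lists past the threshold numbered 0 in each comparison. For day 86 the count of 1 was also 0 with fry, 2 with library totals, no filter, the mean count filter, total reads, a replicate block and only the groups compared, and 0 to 4 when leaving out each library. For day 726 against pre-challenge it was 0 to 1 when leaving out each library. For day 726 against day 86 the count of 2 became 1 with the mean count filter, limma voom, the listed column and called listings, 5 with a replicate block, and 1 to 4 when leaving out each library. Leaving eca-miR-545 out of the DLK1-DIO3 list gave 1, 0 and 2 lists, and 2, 0 and 5 with the replicate block, as with it. The replicate block changed no other call of the fits.

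Direction turned for 3 of the named miRNAs. eca-miR-143, day 726 against pre-challenge, went from -4.17 to 0.73 with limma voom, 0.87 with a replicate block, 2.14 with both L139 libraries left out, and -4.89 to 2.13 when leaving out each library. eca-miR-23b ranged from -0.27 to 2.60 and the unnamed molecule from -2.34 to 9.51 when leaving out each library, each turning without the day 726 library of L140. Library totals alone moved the median of all miRNAs from -0.16 to -0.43 (day 86 against pre-challenge), from -0.04 to 0.10 (day 726 against pre-challenge) and from 0.18 to 0.53 (day 726 against day 86), and upper-quartile scaling moved the first to -0.03 and the last to 0.05. Detection was limited at this size: simulated 4-fold changes were mostly missed.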

Other observations

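Outside the annotated miRNAs, the candidate loci of the files held 2.16 to 26 reads per 100 annotated reads. The most abundant candidate, aauggauuuuuggagcaggg on chromosome 11 from 19987576 to 19987616, has the same seed as hsa-miR-1246 in the files. It had 31690, 187467 and 283194 reads in the pre-challenge libraries of L136, L139 and L140, 115427, 18704 and 576809 in those of day 86, and 18634 and 14914 in the day 726 libraries of L136 and L140. The candidate uuuguucguucggcucgcgug, listed with the seed of hsa-miR-375 on chromosome 6 from 8569813 to 8569868, had reads in all 8 libraries, from 956 to 3583. The epithelial list as fixed names miR-375, but its test and its share of reads do not include this candidate. In CPM of annotated reads, the first was at 7662 and 11430 at day 726 against 11660 to 165500 before challenge, and the second at 815.4 and 732.4 against 899.5 to 2595. Of the 40 most abundant candidates, 3 lay below every pre-challenge library in both day 726 libraries, these 2 and gcaggagaugcuguggacccc, and 0 did in all day 86 libraries; 0 lay above them at either time. These are values without a test. With 2 libraries at day 726 and 3 before challenge, random order alone would place some of the 40 candidates so. The count is therefore no sign of a drop at day 726.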
